A study of Caenorhabditis elegans with 8 samples.

How the data were processed

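Total RNA from 8 populations of wild-type young adult C. elegans was measured, 4 raised on control medium and 4 on medium with a lawn of B. animalis subsp. lactis. Per the labels' protocols, worms were broken by sonication, RNA was isolated with a column kit, and 300 ng per sample was biotin-labelled with the 3' IVT Express protocol and hybridised to Affymetrix C. elegans Genome Arrays. Per the submitters' processing notes, values were made with RMA, which corrects the background, normalizes between arrays by quantiles and summarises the probes of a probe set, and the notes also name limma; versions are not given in the sources used here. The deposited table held 22625 probe sets and 8 sample columns. The log base of the deposited values is not stated and was taken as log2 from the spikes of known concentration added at hybridisation: their values rose by 0.80 to 0.96 per doubling of concentration, under the rise of 1 that log2 allows, and by 1.15 to 1.38 per unit of the natural log of concentration, over the rise of 1 that a natural log allows. The deposited table gave no detection calls, so no level was called absent, and values near either end of the scale can compress differences.

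All columns were matched to samples through the sample identifiers that serve as column names, and 0 columns of per-sample values were left unmatched. Groups were taken from the culture medium in the labels. Replicates 1 to 4 are names given in the order of the samples, and they do not pair samples. The 77 Affymetrix control probe sets were left out of the tests, which left 22548. Gene symbols came from the platform annotation: 20766 probe sets had 1 symbol, 887 several and 895 none. Of those with 1 symbol, 20701 were matched by gene identifier to the RefSeq annotation of assembly WBcel235, which was used for names only, and 65 kept the older symbol. A gene was represented by its probe set with the highest mean over all 8 arrays among those with 1 symbol, which gave 17118 genes, 2981 of them with more than 1 probe set. Of the 120 genes that changed, 10 had more than 1 probe set and in 1 of these the probe sets differed in sign. Probe sets whose names end in a mark for shared or cross-hybridising probes can read several related genes, which applies to 6711 of the probe sets and to 88 of the 150 that changed; 27 of the 150 named several genes and 2 named none.

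Differences are B. lactis minus control, computed with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default prior, no covariates, all 8 samples), with Benjamini-Hochberg adjustment over all probe sets or all genes and a threshold of 0.05. Fold values are 2 to the power of the log2 difference. Gene lists were compared with all other genes by limma's camera with a preset correlation of 0.01 between genes and again with a correlation estimated for each list, adjusted over the 40 lists, each of which had to have at least 3 measured members. Counts within a list are given over all genes and, where said, adjusted over the list alone. Means of list values and of quality measures were compared by exact two-sided permutation tests, and p-values of single genes and lists come from limma unless named otherwise.

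The tests, the gene lists, the named genes and the alternatives were fixed before the data were examined, except those said to be chosen later. The genes named are the 12 largest rises and 12 largest falls past the threshold with groups that do not overlap (7 genes fell in all), the 4 members with the smallest p of each list described, and a fixed set of fat metabolism, yolk and stress genes. The text leaves out some of these members where they add nothing. The other settings fixed then were filters on dim probe sets, quantile normalization again, centring arrays on their medians, eBayes with trend and robust options, array weights, a block of neighbouring label numbers, the label number as a covariate, leaving out each sample, stricter thresholds, the mean over a gene's probe sets, unshared probe sets, and the estimated correlation. Added after seeing the data were the fits without control 1 and B. lactis 1 together and the count of probe sets free of shared endings.

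The fits were tested on simulated data drawn from the real means and residual spreads with 200 changed features. In the gene simulation of 17118 genes, changes of 0.5, 1, 2 and 3 on the log2 scale were called in 42%, 86%, 100% and 100% of 50 genes each, with 10 false calls. In the probe set simulation of 22548 probe sets the shares were 28%, 86%, 98% and 100%, with 9 false calls. A list of simulated glutathione transferases shifted by 0.3 was called by camera (adjusted p = 1.2e-25, and adjusted p = 0.000536 with an estimated correlation); of the other 39 lists, 1 was called with the preset and 0 with the estimated correlation. Genes were drawn independently, so this cannot show how often the preset test calls lists whose members vary together. In the real data the estimated correlation was 0.232 for the collagens and 0.139 for the sperm list.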

Results

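Gene expression was measured on 8 Affymetrix C. elegans Genome Arrays, each hybridised with labelled total RNA from a population of N2 worms, the standard wild-type laboratory strain of the nematode Caenorhabditis elegans. Control worms (4 samples) grew on nematode growth medium, the usual agar for this animal. Treated worms (4 samples, called B. lactis worms here) grew on the same medium carrying a lawn of a Bifidobacterium animalis subspecies lactis strain, a lactic acid producing gut bacterium. Both groups were grown from the egg for 3 days at 20 °C and collected as young adults. The comparison asked which transcripts differed between worms raised with and without this bacterium. The labels do not name the food on the control plates, nor whether the treated plates carried that food as well, so a difference below covers any change of food between the groups. The labels do not say whether the samples of a group came from separate cultures, so the p-values below measure only the spread between these samples, which may be technical.

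Values were log2 expression values per probe set, with array medians between 1.82 and 1.89. Pairwise Pearson correlations across probe sets, which are not independent replicates, lay between 0.979 and 0.997, and no pair of the 28 was identical. The number of arrays limits the precision: the median standard error of a gene's log2 difference was 0.12. The control spikes added at hybridisation averaged 8.86 on control 1 and 6.70 on B. lactis 1, against 5.43 to 5.85 on the other 6 arrays. The probe sets for poly-A spikes, which are meant to be added to the RNA before labelling, averaged 2.14 to 2.57 on all 8 arrays. The 3' minus 5' difference of the actin control probe sets, a sign of RNA quality, was 1.34 ± 0.19 (SD, n = 4) in controls and 1.11 ± 0.21 (SD, n = 4) in B. lactis worms (exact permutation p = 0.2, two-sided).

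**Figure D1:**
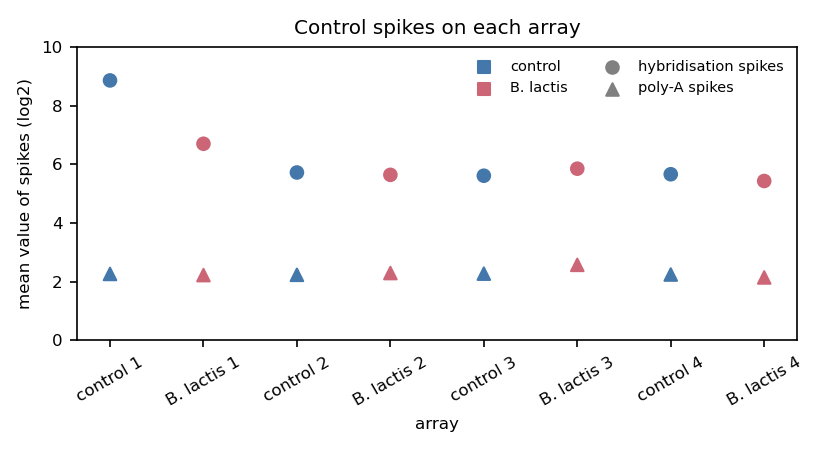
Mean log2 value of the control spikes (vertical axis) on each of the 8 arrays (horizontal axis). Circles are for spikes added at hybridisation and triangles for poly-A spikes, which are meant to be added before labelling. Blue marks control and red marks B. lactis arrays. The hybridisation spikes averaged 8.86 on control 1 and 6.70 on B. lactis 1, and the poly-A spikes stayed between 2.14 and 2.57 on all 8 arrays.

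Worms raised on B. lactis had more signal on the shared probe sets of the major sperm protein family. They had more signal for 9 of 146 cuticle collagens, among them col-129, col-81 and col-139 on shared probe sets. They had more transcript of 4 of 26 proteases, and less of the pud genes and of 5 others, among them cyp-35C1, irg-4 and mtl-2. Among the largest rises that passed the test were msp-76, which rose 8.71-fold, and col-129, a cuticle collagen, which rose 4.25-fold. The largest fall was that of pud-3, whose name stands for a protein raised in daf-2 insulin receptor mutants; it fell by 1.98 on the log2 scale. Of 17118 genes, 120 changed, 7 of them lower and the rest higher in B. lactis worms (limma, Benjamini-Hochberg adjusted p under 0.05). Of 22548 probe sets, 150 changed, 141 higher and 9 lower. The median log2 difference over all probe sets was -0.01. Leaving out 1 array moved the number of genes by over 1.5 times for control 2 (72 genes), control 4 (78), B. lactis 2 (69) and B. lactis 4 (72), and weighting the arrays by their quality raised it to 287. On probe sets free of the endings that mark shared probes, 60 genes changed; without control 1 and B. lactis 1 together, a check chosen after seeing the data, 143 genes changed, 98 of them among the 120.

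The sperm list held the clearest group. Major sperm proteins are small cytoskeletal and signalling proteins made by sperm. All 23 genes named msp that could be measured rose on shared probe sets, with log2 differences from 1.29 to 3.12, which are 2.44-fold to 8.71-fold. Their mean log2 value was 3.98 ± 0.46 (SD, n = 4) in controls and 6.62 ± 0.31 (SD, n = 4) in B. lactis worms, a 6.23-fold difference (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 allows). The 12 largest rises past the test were all msp genes; msp-76 went from 4.17 ± 0.66 to 7.29 ± 0.38 (SD, n = 4 each; adjusted p = 0.000266), msp-38 rose 8.22-fold (adjusted p = 0.000184) and msp-31 rose 7.81-fold (adjusted p = 9.09e-05). The others of the 12 were msp-33, msp-36, msp-77, msp-78, msp-19, msp-59, msp-152, msp-55 and msp-53, with rises of 6.81-fold to 7.55-fold. The sequences of this family are nearly alike and all 23 genes were read by probe sets marked as shared, so the number of separate msp genes that changed cannot be established. Of the 32 probe sets naming an msp gene 31 rose, and the exception was the 1 without a shared ending. It reads msp-32, named here after its values were seen, at 1.79 ± 0.18 in controls and 1.97 ± 0.33 in B. lactis worms (SD, n = 4 each; log2 difference 0.19, adjusted p = 0.789), near the array medians, while the shared probe set of msp-32 rose by 1.29 on the log2 scale.

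Of the 69 measured members of the sperm list, which also holds the spe and ssp genes of sperm development, 24 rose, 0 fell and 45 did not pass; 33 rose when p-values were adjusted over the list alone. The member outside the msp family that rose was ssp-10, another sperm-specific gene, named here after its values were seen (1.75-fold, adjusted p = 0.00605). It too was read by a probe set marked as shared. The list rose as a whole (median log2 difference 0.34, mean difference 1.99-fold; camera adjusted p = 2.63e-32, and adjusted p = 0.0516 with an estimated correlation). Among the 30 probe sets naming a spe gene 0 passed in limma and 1 had an unadjusted p under 0.05 (median log2 difference -0.04). Among the 30 sperm genes outside the msp family with unshared probe sets 0 passed in limma and 5 had an unadjusted p under 0.05 (median log2 difference 0.09). The 5 were ssq-1 (0.81, limma adjusted p = 0.0764), ssp-35 (0.79), ssp-16 (0.66), ssp-19 (0.48) and ssp-34 (0.34). The other differences lay between -0.22 and 0.19, and 18 of all 30 were positive.

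Cuticle collagens, which form the worm's outer coat, also rose as a list. Of 146 members, 9 rose, 0 fell and 137 did not pass; adjusted over the list alone, 33 rose and 1 fell. The count of 9 went to 4 without control 2, B. lactis 2 or B. lactis 4, to 6 without control 3 or control 4, and to 18 with array weights. On unshared probe sets 3 of 91 rose. The genes col-129, col-81 and col-139 were read only by shared probe sets, so they were not measured there. The median log2 difference was 0.27, and 17 of the 146 members were negative (camera adjusted p = 2.14e-25, and adjusted p = 0.166 with an estimated correlation). The value of col-81 went from 3.96 ± 0.09 to 6.02 ± 0.16 (SD, n = 4 each; 4.19-fold, adjusted p = 4.07e-06), that of col-139 from 4.90 ± 0.13 to 6.76 ± 0.12 (3.64-fold, adjusted p = 6.85e-06) and that of col-142 from 4.70 ± 0.44 to 6.33 ± 0.24 (3.08-fold, adjusted p = 0.00219). Of the 68 molting factors and hedgehog-related proteins, grd-10 (2.43-fold, adjusted p = 0.00545) and grd-3 (1.44-fold, adjusted p = 0.0341) rose, 0 fell, and 3 rose and 1 fell adjusted over the list alone. The grd genes encode ground-like secreted proteins. The call of grd-3 was lost in 12 of its 19 alternatives, which included leaving out each single array, with adjusted p of up to 0.132. That list passed the preset test with a median of 0.09 (camera adjusted p = 0.0317, and adjusted p = 0.359 with an estimated correlation), and its call was lost without control 1 (adjusted p = 0.106), control 3 (0.0606), control 4 (0.0978), B. lactis 2 (0.0564) or B. lactis 3 (0.177), with array weights (0.0714) and on unshared probe sets (0.0552).

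Oocyte and yolk genes lay on the lower side. Of 36 oocyte, eggshell and germline genes, 33 had negative differences and 0 passed the test over all genes or adjusted over the list alone (limma), while 3 had an unadjusted p under 0.05. In the preset test the list fell as a whole by a small amount (median log2 difference -0.15, camera adjusted p = 1.75e-05). With an estimated correlation the camera adjusted p was 0.209. The array means of the list gave an exact two-sided permutation p of 0.0571, with 8.14 on both control 1 and B. lactis 4. Its members with the smallest p were chs-1, a chitin synthase of the eggshell (log2 difference -0.23, adjusted p = 0.431), the eggshell proteoglycan cpg-2 (-0.19, adjusted p = 0.522), the RNA-binding protein mex-3 (-0.22, adjusted p = 0.525) and the oocyte maturation factor oma-1 (-0.25, adjusted p = 0.553). All 5 measured vitellogenins, the yolk proteins, had negative differences; 0 passed over all genes and 2 fell adjusted over the list alone. These were vit-5 (11.57 ± 0.05 against 11.33 ± 0.02, SD, n = 4 each) and vit-4 (11.47 ± 0.04 against 11.24 ± 0.06), whose 3 probe sets differed in sign. Both lay close to the array maxima of 11.60 to 11.96, where signals can saturate. The genes vit-1, vit-2 and vit-6 had log2 differences of -0.08, -0.10 and -0.04 and did not pass. The yolk list fell in the preset test (median -0.10; camera adjusted p = 0.0172, and adjusted p = 0.209 with an estimated correlation), and its call was lost without control 1 (adjusted p = 0.0665), without control 1 and B. lactis 1 together (0.0606) and on unshared probe sets (0.154). For vit-3 no value of its own was analysed here. The early embryo list did not pass (18 members, median -0.05, camera adjusted p = 0.169).

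Of the 7 genes that fell, the pud genes fell most. Both pud-3, from 6.22 ± 0.36 to 4.24 ± 0.41 (SD, n = 4 each; adjusted p = 0.000777), and pud-4, which fell by 1.78 on the log2 scale (adjusted p = 0.00129), passed. The 4 probe sets naming pud genes, chosen after their values were seen, all fell, with log2 differences between -1.98 and -1.21. The xenobiotic-type cytochrome P450 gene cyp-35C1 fell by 1.08 on the log2 scale (SE 0.13, adjusted p = 0.00141), and irg-4, an infection response gene, fell by 1.26 (SE 0.22, adjusted p = 0.0233). The metallothionein mtl-2, which binds metal ions, fell by 0.74 (SE 0.14, adjusted p = 0.0385), nspe-7, of a nematode-specific peptide family, by 0.71 (adjusted p = 0.0388), and the short-chain dehydrogenase dhs-23 by 0.61 (adjusted p = 0.0458). The calls of pud-3, pud-4 and cyp-35C1 held in each alternative that measured them; those of irg-4, mtl-2, nspe-7 and dhs-23 were lost when any of several single arrays was left out, with adjusted p of up to 0.0878, 0.143, 0.141 and 0.144 over the alternatives.

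**Figure D2:**
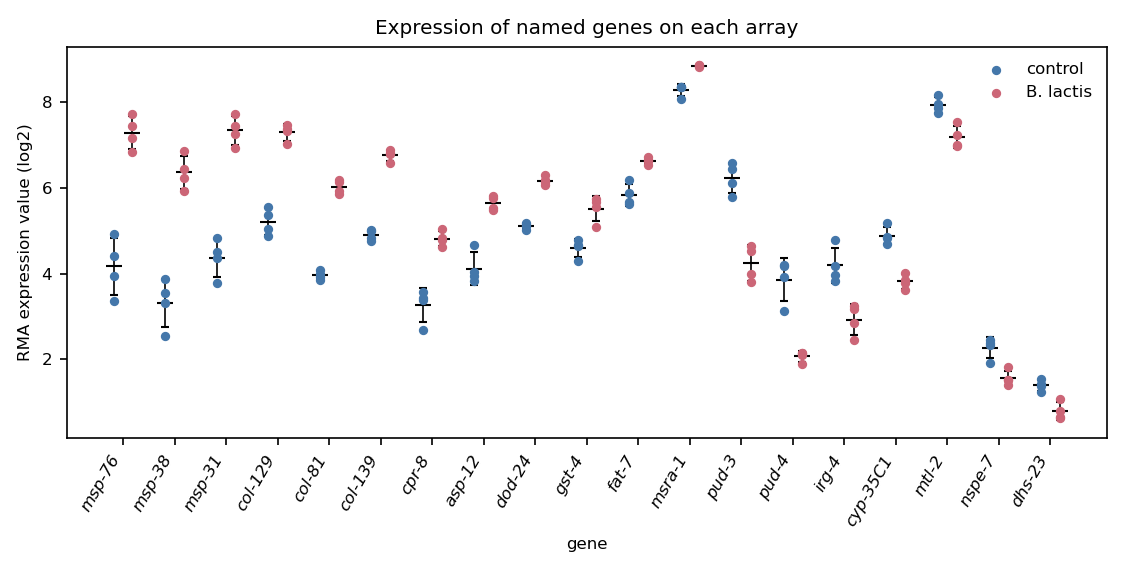
RMA expression value (vertical axis, log2) of 19 named genes (horizontal axis) on each array; dots are single arrays, blue for control and red for B. lactis, and black bars give the mean and SD of 4 arrays. In each gene shown the 2 groups do not overlap, as for msp-76 (means 4.17 and 7.29) and pud-3 (means 6.22 and 4.24).

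Genes of fat metabolism showed few single changes. The stearoyl-CoA desaturase fat-7 rose from 5.84 ± 0.26 to 6.63 ± 0.08 (SD, n = 4 each; 1.73-fold, adjusted p = 0.0146); the call was lost without control 2, control 4 or any of B. lactis 2, 3 and 4, at most to an adjusted p of 0.0677. The related desaturase fat-5 did not pass (log2 difference 0.54, adjusted p = 0.0956), nor did fat-6 (0.20), fat-1 (-0.05), fat-2 (-0.01), fat-3 (-0.05) or fat-4 (-0.02). Of 23 fatty acid synthesis genes 1 rose, 0 fell, and 3 rose adjusted over the list alone (median 0.08; camera adjusted p = 0.0141, and adjusted p = 0.209 with an estimated correlation). The list's call was lost without B. lactis 2 (adjusted p = 0.0717) and on unshared probe sets (median 0.01, adjusted p = 0.243).

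Of 23 peroxisome genes, pmp-5, an ABC transporter of the peroxisomal membrane family, rose 1.64-fold (adjusted p = 0.0106) and 0 fell; 4 rose adjusted over the list alone. The list rose (median 0.17, 18 of 23 members positive; camera adjusted p = 7.62e-05, and adjusted p = 0.166 with an estimated correlation). The peroxisomal acyl-CoA oxidase acox-1.1 did not pass over all genes (log2 difference 0.50, SE 0.11, adjusted p = 0.0765), and neither did daf-22 (0.29), maoc-1 (0.16) or the catalase ctl-2 (-0.01). The mitochondrial beta-oxidation list did not pass (31 members, median -0.03, mean 0.02, camera direction up, adjusted p = 0.838). No member passed over all genes, and 2 rose and 1 fell adjusted over the list alone. The list's acyl-CoA synthetase acs-2 had a log2 difference of -0.49 (limma adjusted p = 0.107), and the fat metabolism regulator nhr-49 of -0.05. The lipase list did not pass (29 members, median -0.04, mean 0.04, camera direction up, adjusted p = 0.864), though lips-10, a lipase-like gene, rose 1.8-fold (adjusted p = 0.0178; lost in 5 of 19 alternatives); lipl-4 had a difference of -0.01. Lipid storage genes (26 members, median 0.02, camera adjusted p = 0.183) and the tricarboxylic acid and glyoxylate cycles (23 members, median 0.04, camera adjusted p = 0.59) did not pass, and neither had a member that passed in limma, with 6 and 1 members at an unadjusted p under 0.05.

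Of the detoxification lists, the glutathione transferases and the UDP-glucuronosyltransferases passed the preset test and the cytochrome P450 genes did not. Of 45 glutathione S-transferases, gst-4, a widely used reporter of oxidative stress, rose from 4.59 ± 0.21 to 5.51 ± 0.29 (SD, n = 4 each; 1.89-fold, adjusted p = 0.0189), and gsto-1, of the omega class, rose 2.05-fold (adjusted p = 0.0199). No member fell, and 5 rose adjusted over the list alone (median 0.15; camera adjusted p = 5.19e-05, and adjusted p = 0.166 with an estimated correlation). The call of gst-4 was lost without control 2, 3 or 4 or B. lactis 2, 3 or 4, at most to an adjusted p of 0.0837. Of 64 UDP-glucuronosyltransferases, which couple sugar acids to small molecules, ugt-63 (2.04-fold, adjusted p = 0.00882) and ugt-13 (1.88-fold, adjusted p = 0.013) rose, 0 fell, and 6 rose adjusted over the list alone (median 0.09; camera adjusted p = 0.00143, and adjusted p = 0.0516 with an estimated correlation). The control mean of ugt-13, 1.27, lay below the array medians of 1.82 to 1.89. The 73 cytochrome P450 genes did not pass as a list (median -0.02, camera adjusted p = 0.0724); 1 fell over all genes and 3 fell adjusted over the list alone. The antioxidant list missed the threshold (32 members, median 0.09, camera adjusted p = 0.0538). Its member msra-1, a methionine sulfoxide reductase, rose 1.49-fold (limma adjusted p = 0.0178), and the superoxide dismutase sod-3 had a log2 difference of 0.02. Adjusted over the list alone 2 rose and 0 fell. Heat shock proteins (12 members, median -0.08, mean 0.02, camera direction down, adjusted p = 0.742) and the organelle unfolded protein response (17 members, median -0.10, camera adjusted p = 0.219) did not pass.

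Several proteases rose. Of 26 aspartyl and cathepsin-like proteases, 4 rose and 0 fell. The aspartyl protease asp-12 went from 4.11 ± 0.38 to 5.66 ± 0.16 (SD, n = 4 each; 2.91-fold, adjusted p = 0.000968), and the cathepsin B-like cpr-8 from 3.26 ± 0.39 to 4.81 ± 0.17 (2.94-fold, adjusted p = 0.00117). The other members that rose were asp-8 (2.09-fold, adjusted p = 0.0288) and cpr-4 (1.59-fold, adjusted p = 0.013), whose calls were lost in 6 and 4 of 19 alternatives. For asp-8 the control mean of 1.48 lay below the array medians of 1.82 to 1.89. Adjusted over the list alone 7 rose, and the list passed the preset test with a median of 0.07 and a mean of 0.23 (camera adjusted p = 0.00749, and adjusted p = 0.209 with an estimated correlation).

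Genes reported to be induced by bacterial infection moved in both directions. Of 19 members, dod-24, a gene downstream of the transcription factor DAF-16 (2.08-fold, adjusted p = 0.000184), and C17H12.8 (1.73-fold, adjusted p = 0.00769) rose and irg-4 fell; adjusted over the list alone 4 rose and 1 fell. The list passed the preset test (median 0.20; camera adjusted p = 0.0079, and adjusted p = 0.209 with an estimated correlation), and its call was lost without B. lactis 3 (adjusted p = 0.0582) and on unshared probe sets (0.0906). Antimicrobial peptides did not pass as a list (48 members, median -0.01, mean 0.06, camera direction up, adjusted p = 0.256). The saposin-like spp-23 rose 1.58-fold (limma adjusted p = 0.0337, lost in 8 of 19 alternatives), and 5 rose and 1 fell adjusted over the list alone. No member passed over all genes among 16 lysozymes (camera adjusted p = 0.0887), 220 C-type lectins (0.742) or 52 intracellular pathogen response genes (0.965). That last list had a median of 0.04 and a mean of 0.01, with camera direction down. In limma 5, 16 and 3 members of the 3 lists had an unadjusted p under 0.05. Adjusted over each list alone, 1, 2 and 0 members rose and 0 fell. The 13 genes reported to be raised by DAF-16 did not pass (median -0.01, camera adjusted p = 0.156). Over all genes mtl-2 was the member that fell, and 2 fell adjusted over the list alone.

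The lists of intestine, pharynx, muscle and neuron markers passed the preset test, higher in B. lactis worms. Control 1 lay below the other controls in the intestine list (5.33, the others 5.64 to 5.68) and the neuron list (2.71, the others 2.92 to 2.93), and without it the median differences were 0.20 for intestine, 0.22 for pharynx, 0.23 for muscle and 0.05 for neuron markers. Of 14 intestine markers, the intermediate filament ifc-2 (1.69-fold, adjusted p = 0.0146) and the proton pump subunit vha-6 (1.56-fold, adjusted p = 0.0147) rose and mtl-2 fell (median 0.30; camera adjusted p = 8.86e-05, and adjusted p = 0.209 with an estimated correlation); adjusted over the list alone 5 rose and 1 fell. The call of ifc-2 was lost without B. lactis 2 (adjusted p = 0.0677), 3 (0.0556) or 4 (0.0598), and with the mean over its 3 probe sets its log2 difference went from 0.76 to 0.40 (adjusted p = 0.132). That of vha-6 was lost without control 2 (0.0569), control 3 (0.0595), B. lactis 2 (0.0677) or B. lactis 4 (0.0595). Of 16 pharynx markers, the troponin C gene tnc-2 rose 1.4-fold (adjusted p = 0.0326), 7 rose and 1 fell adjusted over the list alone (median 0.33; camera adjusted p = 1.75e-05, and adjusted p = 0.166 with an estimated correlation). Among 15 body wall muscle markers 0 passed over all genes in limma, 6 had an unadjusted p under 0.05 and 2 rose adjusted over the list alone (median 0.18; camera adjusted p = 7.62e-05, and adjusted p = 0.0516 with an estimated correlation). The 18 neuron markers (median 0.15; camera adjusted p = 0.0227, and adjusted p = 0.31 with an estimated correlation) and the 83 neuropeptides (median 0.15; camera adjusted p = 6.95e-05, and adjusted p = 0.271 with an estimated correlation) rose as lists in the preset test, with no member past limma's threshold and 2 and 21 members at an unadjusted p under 0.05. The neuron call was lost without control 1 (adjusted p = 0.131), B. lactis 1 (0.0777) or B. lactis 2 (0.0567), with array weights (0.167) and on unshared probe sets (median 0.02, adjusted p = 0.427). The call of tnc-2 was lost in 13 of its 19 alternatives, which included leaving out each array except control 1, with adjusted p of up to 0.109.

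The mitochondrial respiratory chain list rose in the preset test (40 members, median 0.10, camera adjusted p = 0.00401). With an estimated correlation its camera adjusted p was 0.271. It had no single call in limma and 4 members at an unadjusted p under 0.05. Of 18 vacuolar ATPase genes, which acidify organelles, vha-6 rose (median 0.13; camera adjusted p = 0.00614, and adjusted p = 0.209 with an estimated correlation), and the list's call was lost without B. lactis 2 (adjusted p = 0.0564) and on unshared probe sets (median 0.00, adjusted p = 0.932). The list of the canonical propionate pathway and methionine cycle passed the preset test (21 members, median 0.09, camera adjusted p = 0.0141). With an estimated correlation its camera adjusted p was 0.209. In limma 0 members passed over all genes, 4 had an unadjusted p under 0.05, and 1 rose adjusted over the list alone. The list's call was lost without control 1 (camera adjusted p = 0.0665), without B. lactis 2 (0.0717) and without control 1 and B. lactis 1 together (0.0648). It was also lost on unshared probe sets (0.112) and on probe sets above the median level (0.112). The propionate shunt, which worms use when vitamin B12 is low, did not pass (5 members, median 0.02, camera adjusted p = 0.743); its acyl-CoA dehydrogenase acdh-1 had a log2 difference of -0.07. Tyrosine breakdown lay just under the threshold (4 members, median 0.15; camera adjusted p = 0.0473, and adjusted p = 0.31 with an estimated correlation) and its call was lost without any of control 1, 3 and 4 and B. lactis 1 and 2, at most to an adjusted p of 0.148. It was lost in 11 settings with the preset correlation, with a camera adjusted p of 0.17 without control 1 and B. lactis 1 together. Kynurenine breakdown (10 members, camera adjusted p = 0.063; tdo-2 at a log2 difference of 0.16), insulin-like peptides (24 members, 0.156), short-chain dehydrogenases (30 members, 0.81), nuclear hormone receptors (254 members, camera direction down with a mean of 0.00, 0.838) and cytosolic ribosomal proteins (75 members, median 0.00, 0.965) did not pass. Among them the short-chain dehydrogenase dhs-26 (1.88-fold, adjusted p = 0.0326) and the nuclear receptor nhr-90 (1.44-fold, adjusted p = 0.0198) rose, each with a call lost in 6 alternatives. For nhr-90 the control mean of 1.32 lay below the array medians of 1.82 to 1.89.

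**Figure D3:**
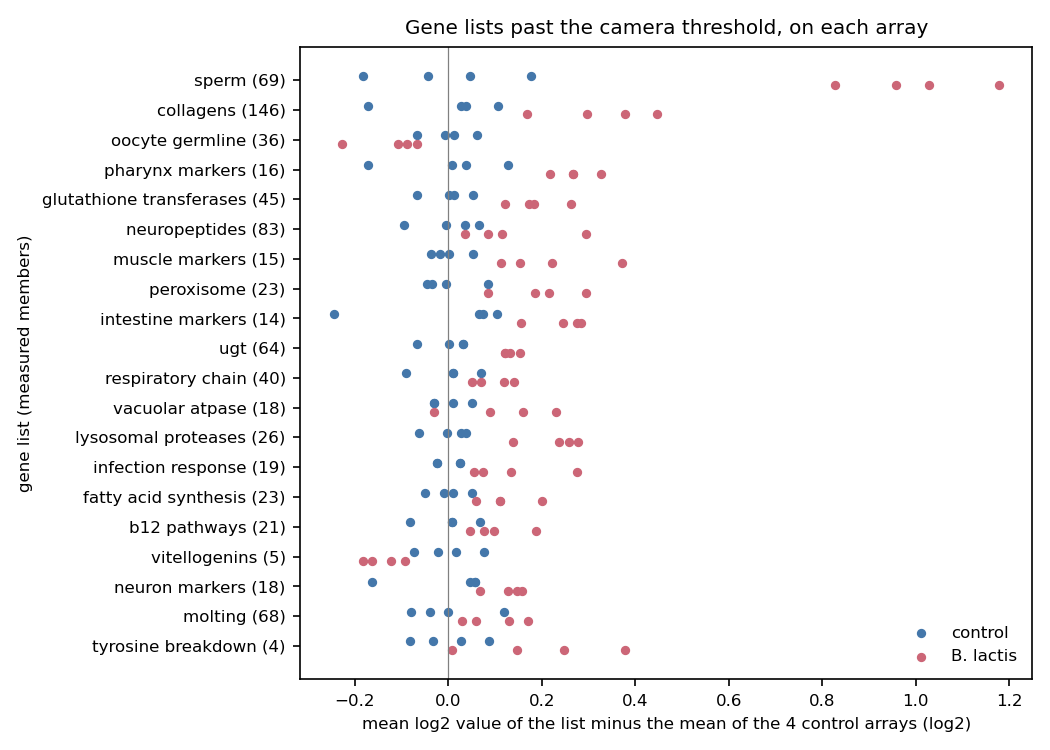
Mean log2 value of each gene list on each array (dots, blue for control and red for B. lactis) minus the mean of the 4 control arrays (horizontal axis, log2), for the 20 lists past the camera threshold with the preset correlation (vertical axis, measured members in parentheses). The sperm list is highest in B. lactis worms, with a mean difference of 1.99-fold, and the oocyte germline and vitellogenin lists lie below the control mean in all 4 B. lactis samples.

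In all, 20 of the 40 lists passed the camera test with the preset correlation, 18 higher and 2 lower in B. lactis worms. With a correlation estimated for each list 0 passed (smallest adjusted p 0.0516), while 9 had an unadjusted p under 0.05. An exact permutation test of the list means, whose smallest possible p is 0.0286, gave that p for 16 of the 40 lists. No list passed after adjustment over the 40 (smallest adjusted p 0.0715). Among the 20 lists, that test gave 0.114 for molting factors and 0.0857 each for the respiratory chain, vacuolar ATPase and tyrosine breakdown. It gave 0.0571 each for the oocyte list, the neuropeptides and the list of the propionate pathway and methionine cycle.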

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

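The tests of the control 1 spikes were chosen after the result was seen. In 24 of 456 sets of 4 samples the highest or lowest sample lay far from the other 3, by a gap that took up most of the range of the 4; about 23 are expected by chance, which marks about 1 set in 20. Of the 24, 13 were in control 1.

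The largest was the mean of the hybridisation control spikes, 8.86 on control 1 against 5.61 to 5.72 on the other control arrays. Their 18 probe sets were higher there by 3.19 ± 0.40 (SD). The 24 probe sets for poly-A spikes, meant to be added to the RNA before labelling, were shifted by 0.01 ± 0.42 (SD). The 7 of them with a mean above 3 were shifted by -0.11 ± 0.21 (SD). The poly-A spikes averaged 2.14 to 2.57, close to the array medians of 1.82 to 1.89, where a shift is hard to see, so their small shift decides little. Less labelled worm RNA on that array and a larger volume of hybridisation spikes could both be the source, and these values cannot tell them apart. Control 1 also stood apart on the first principal component, which held 37.7% of the variance (-47.5, against -2.9 to 0.9 for the other controls). No biological explanation was tested for this array.

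Control 1 was also far from the other controls in the mean of 3 lists, lipid storage (5.08, the others 5.18 to 5.19), intestine markers (5.33, the others 5.64 to 5.68) and neuron markers (2.71, the others 2.92 to 2.93). Among named genes it was low in hgo-1 (5.72), irg-3 (3.18), lbp-3 (5.21), nlp-20 (3.75) and ugt-13 (0.85), and high in lipl-4 (0.98), nhr-90 (1.46), skr-3 (4.42) and wrt-7 (1.56). Control 2 was low in fat-2 (7.95), msra-1 (8.06) and pmp-5 (6.26), and control 4 was high in acl-7 (3.66). B. lactis 3 was low in acdh-1 (8.76) and high in acs-2 (4.64), acsd-1 (3.09) and metr-1 (6.66). B. lactis 2 was high in asg-2 (8.09), B. lactis 1 was low in mev-1 (7.94) and B. lactis 4 was high in ugt-41 (3.11).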

How the results depend on the processing

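The fits without control 1 and B. lactis 1 together and the count on unshared probe sets were chosen after seeing the data. Changed probe sets (150) and genes (120) moved to 349 and 287 with array weights, 72 and 59 at an adjusted p under 0.01, 78 and 56 with a log2 difference of at least 1 as well, and 41 and 60 on unshared probe sets, where fewer were tested; why array weights raised the counts was not tested. Leaving out 1 array gave 87 to 143 probe sets and 69 to 126 genes; the lowest probe set counts were without control 2 (87), B. lactis 2 (91) and B. lactis 4 (93), and fewer samples were then fitted. Lists past the threshold went from 20 to 0 with an estimated correlation, and 12 of the 20 passed in every other setting. The test of the vacuolar ATPase list turned direction on unshared probe sets (6 members, median 0.00, adjusted p = 0.932), and that of the intracellular pathogen response list on probe sets above the median level (7 members, median 0.16, adjusted p = 0.0465); the cause was not tested. The stricter thresholds are left out of the next counts, and pmp-5 (limma adjusted p = 0.0106) would miss 0.01. Of the 48 named genes that passed, 29 passed in each alternative that measured them and 19 were lost in some: fat-7, gst-4, gsto-1, irg-4, mtl-2, nspe-7, dhs-23, ifc-2, vha-6, tnc-2, msra-1, asp-8, cpr-4, ugt-13, spp-23, dhs-26, nhr-90, lips-10 and grd-3, to an adjusted p of at most 0.144. With fewer samples fitted, 4, 14, 12 and 14 of them were lost without control 1, 2, 3 and 4, and 11, 19, 10 and 17 without B. lactis 1, 2, 3 and 4. With neighbouring label numbers as a block, 153 probe sets, 133 genes and 19 lists passed; deviations of neighbouring samples correlated at 0.25, 0.25, -0.08 and 0.00, so the numbers were not taken as pairs. Without control 1 and B. lactis 1 together, 144 probe sets (109 of the 150), 143 genes (98 of the 120) and 21 lists passed. Centring moved the median difference of all probe sets from -0.010 to -0.045. The deposited values carry no background level, so differences of genes near the lower end are limits on what could be seen.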

Other observations

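Of the tests in this part, those of the hrg genes, of gene families by name and of probe set groups were chosen after the results were seen. Of 11 measured genes named hrg, for heme-responsive, 3 rose and 8 did not pass, among them hrg-13 (log2 difference -0.21) and hrg-14 (-0.18). The family passed camera with the preset correlation (adjusted p = 1.62e-06, and adjusted p = 0.415 with an estimated correlation). The gene with the smallest p of all was hrg-7, which encodes a secreted aspartic protease-like protein that signals heme status between tissues; it rose from 6.23 ± 0.07 to 8.40 ± 0.14 (SD, n = 4 each; 4.48-fold, limma adjusted p = 2.42e-06). The heme transporter hrg-1 also rose, from 3.63 ± 0.40 to 5.20 ± 0.10 (SD, n = 4 each, 2.97-fold, limma adjusted p = 0.000777). So did the heme transporter hrg-4, from 1.65 ± 0.16 to 2.63 ± 0.36 (SD, n = 4 each, 1.97-fold, limma adjusted p = 0.0189). The probe set of hrg-1 is marked as shared, and the control mean of hrg-4 lay below the array medians of 1.82 to 1.89. Other genes outside the lists that rose, chosen after their values were seen, were far-3 and ctsa-4.1. The gene far-3, of a fatty acid and retinol binding protein, rose 2.96-fold (limma adjusted p = 0.00882) on a probe set marked as shared. The gene ctsa-4.1, of a carboxypeptidase related to cathepsin A, rose 2.51-fold (limma adjusted p = 0.000341).

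Some members of other small families rose beside the msp genes. Of 4 probe sets naming an msd gene, which encode proteins with the major sperm protein domain, 3 rose (median log2 difference 2.08), and of 10 naming an nspd gene, of a nematode-specific peptide family, 6 rose (median 1.33). Of 10 naming an ssp gene 2 rose (median 0.50), of 6 naming an nsph gene 2 rose (median 0.45), and of 30 naming a spe gene 0 rose (median -0.04; limma, 1 at an unadjusted p under 0.05). All 4 msd probe sets, 8 of the nspd probe sets and 6 of the ssp probe sets carry the endings of shared probes. Of 390 families formed by name, 27 passed camera with the preset correlation and 0 with an estimated correlation, nspd at an adjusted p of 0.721 and ssp at 0.619.

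For the higher msp values in B. lactis worms, a read-out shared by near-identical probes was tested on the 30 other sperm genes with unshared probe sets, whose mean log2 difference was 0.11 ± 0.03 (SE, n = 4 per group; exact permutation p = 0.0286), above the set limit of 0.1 by less than its error. That mean pools 5 genes at 0.34 to 0.81 (ssp-16, ssp-19, ssp-34, ssp-35 and ssq-1) with others at -0.22 to 0.19, and 0 passed in limma. Values of other sperm genes cannot show whether msp probe sets read one another. The 1 msp probe set without a shared ending, of msp-32, did not pass (log2 difference 0.19, limma adjusted p = 0.789) but read near the array medians. How many msp genes rose therefore stays open. A read-out shared among msp genes would still need at least 1 of them to rise. The arrays with high spikes are argued against, since without control 1 and B. lactis 1 the mean log2 difference of the msp genes was 2.67, against 2.64 with them. An earlier developmental stage at harvest, in which sperm genes are more and yolk genes less expressed, may account for part of the pattern: the vitellogenin list had a mean log2 difference of -0.14 (exact permutation p = 0.0286) and -0.12 without those arrays, where its camera call was lost (adjusted p = 0.0606), as it was on unshared probe sets (0.154) and with an estimated correlation (adjusted p = 0.209). The largest differences in the vitellogenin list were those of vit-5 and vit-4, which lay close to the array maxima, where signals can saturate. The probe sets of vit-4 differed in sign. An earlier stage stays a hypothesis, since the spe probe sets, of genes also used in sperm development, had a median log2 difference of -0.04, and a direct response to the bacterium is untested.

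The rise of hrg-1, hrg-4 and hrg-7 could come from less heme in the food of the B. lactis worms, since C. elegans cannot make heme and takes it from its food, which the labels do not name for the control plates. The test on other genes reported to rise when heme is low rested on hrg-3 alone, which had a low level (0.61 ± 0.13 against 0.87 ± 0.15, SD, n = 4 each) and a log2 difference of 0.27 (exact permutation p = 0.0857), so heme supply and other effects of the food cannot be told apart here; hrg-2 was not analysed here on its own. The arrays with high spikes are argued against, since without control 1 and B. lactis 1 the mean log2 difference of the 3 genes was 1.54, against 1.57 with them.

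A chance division of these 8 samples into 4 and 4 cannot be fully excluded as the source of the counts of probe sets and genes. With 35 splits the smallest exact p is 0.0286. The other splits mix the 2 groups, which widens their spread and can lower their counts. The comparison of splits says nothing about differences between cultures. Of the 35 splits, 1, the real one, gave as many probe sets (150, highest other 0), 1 gave as many genes (120, highest other 0) and 1 gave as many lists (20, highest other 14). The list count is less firm: another split with no gene past the threshold reached 14 lists, leaving out B. lactis 2 gave 15, and the estimated correlation gave 0.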
